A study of Mus musculus with 11 samples.

How the data were processed

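The samples were 11 preparations of total RNA from adult mouse colon, biotin-labelled and hybridised to an Affymetrix mouse 430 2.0 array, per the labels' protocols and the probe table's header. The labels give 3 groups, control (n = 3), imatinib for 3 h (n = 4) and imatinib for 12 h (n = 4). The deposited values are linear intensities, 1 signal per probe set, and the software and summary method that made them are not given in the sources used here. The values themselves show that each array had been scaled by a single factor, since the mean after trimming 2% at each end was 100 on every array, with no log and no quantile normalization. The table holds 45101 probe sets, 64 of them controls, and 29 of 496111 values were exactly 0. No 2 arrays were identical among the 55 pairs.

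Probe sets were named through the platform annotation, with symbols updated by Entrez number to the RefSeq annotation of GRCm38.p6, in which 99.4% of the numbers were found. Of 45037 probe sets other than controls, 34945 had 1 gene symbol, 932 several and 9160 none, and those with several or none were left out of the gene tests. Each gene was represented by its probe set with the highest mean over the 11 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Coordinates were not used.

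Signals were transformed as log2(signal + 16), so a fold change is on that scale and understates the change of dim genes. The offset of 16 was chosen after seeing that the values were linear and before any test. The mean level of 32.9% of the genes lay below the level of a signal equal to the offset. Genes were tested with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes moderation, 8 residual and 3.99 prior degrees of freedom) on all 11 arrays, which share 1 estimate of the spread, with contrasts of 3 h against control, 12 h against control and 12 h against 3 h. Tests were 2-sided and calls were made at a Benjamini-Hochberg adjusted p under 0.05 with no filter on level. Over all genes tested 15.3%, 13% and 11.6% had arrays that did not overlap between the groups, where chance gives 5.71%, 5.71% and 2.86%. Unadjusted p was under 0.05 for 2735, 2883 and 3231 genes in the 3 contrasts, where 910 would be expected by chance.

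Gene lists, 41 in number, were fixed before the data were examined and cover the study's subject, injection and harvest time, drug exposure, metabolism, cell types of the colon, inflammation, other tissues, region of the colon and RNA quality. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry. Only the glucocorticoid-induced genes at 3 h, the Per and Dbp clock genes at 12 h, and both lists between 12 h and 3 h were called with an estimated correlation. Fry, which tests whether a list's genes move on balance in one direction, called 2, 8 and 8 lists. At 3 h these were the glucocorticoid-induced and posterior Hox genes. At 12 h they were both circadian clock lists and the glucocorticoid-induced, fibroblast, cholesterol synthesis, mitotic, anterior Hox and Eph genes. Between 12 h and 3 h they were both clock lists and the glucocorticoid-induced, immediate early and fibroblast genes. The cholesterol synthesis, skeletal muscle and posterior Hox genes were called there too. Lists of pancreatic acinar markers (16 of 19 measured) and male accessory gland markers (9 of 10 measured) were added after seeing the data. Named genes followed a rule fixed at the same time: a fixed set of 12 genes; per contrast the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups; and up to 4 members of each described list with the smallest p. Predicted genes, receptor families, immune receptor segments and small RNAs were counted but not named.

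Simulated data with the real genes' means and spreads and 200 changed genes were used to test the procedure. Of these 67 changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 18193 genes. For 3 h against control 41.8%, 92.5% and 100% of them were recovered. For 12 h against control these shares were 52.2%, 88.1% and 100%, and for 12 h against 3 h 49.3%, 91% and 100%. Of the calls 7 of 163, 7 of 167 and 12 of 172 were false. The noise was drawn independently for each gene and array. Variation that many genes of an array share was therefore not simulated, and these shares may be too favourable for the real arrays. Alternatives fixed beforehand covered scaling, a level filter, the treatment of probe sets, array weights, the variance prior, the arrays in the fit, a replicate block, leaving out each array, the threshold and the list test. Alternatives added after seeing the data were offsets of 1 and 64, leaving out the 5 arrays high in pancreatic transcripts, and pancreatic, fat and posterior Hox scores as covariates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.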

Results

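Colon from adult C57BL/6 mice was profiled on 11 expression arrays. The control group held 3 arrays from mice before imatinib, and 4 arrays each came from 3 h and from 12 h after an imatinib injection. Imatinib is a tyrosine kinase inhibitor whose targets include the Abl kinases, Kit and the PDGF receptors. The series title places these arrays in work on signalling from EphB receptors to Abl in intestinal tumours. Vehicle-injected mice and controls killed at matched hours were not analysed here, so each comparison with control joins the drug, the injection and the hour of harvest. Control RNA added to the samples also differed between the groups, as given below, so differences in RNA handling are not separated either. The labels number the samples within a group without saying that each came from a separate mouse, so p-values measure the spread between these samples. The signal of 18193 genes was compared, and the median signal of an array lay between 16.8 and 23.9. The number of arrays limits the precision of every value.

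The first comparison asked what differed in colon 3 h after imatinib. The genes Adamts1 and Adamts4, which encode secreted matrix metalloproteases, were among the largest rises at 3 h. Adamts1 had a signal of 32.8 ± 3.35 (SD, n = 3) in control and 330.9 ± 46.6 (SD, n = 4) at 3 h, a log2 change of 2.82 ± 0.14 (SE; limma adjusted p = 3.11e-06). Genes that glucocorticoids induce rose as a group, and Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, went from 407.5 ± 31.1 (SD, n = 3) to 1073 ± 52.6 (SD, n = 4). Of 27 genes of the amino acid stress response driven by the transcription factor ATF4 and of the unfolded protein response 7 rose, while 4 posterior Hox genes and the colonic proton pump gene Atp12a fell. Cyclin D1 (Ccnd1), Abl1, Abl2 and Kit did not pass the test.

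In all, 261 genes rose and 201 fell at 3 h among 18193 tested (limma, adjusted p under 0.05), and 99 of the rises and 20 of the falls were at least 2-fold. After each array was shifted to an equal median 289 rose and 146 fell. No arrays of the groups overlapped for any of the genes named next. The largest rises were Ptx3 (a secreted pattern recognition protein, log2 change 3.25 ± 0.20 SE), Kcne4 (a potassium channel subunit, 3.14 ± 0.20 SE), the metalloprotease Adamts4 (2.96 ± 0.25 SE), Nfil3 (a transcription factor that represses clock output, 2.95 ± 0.33 SE). Next came the small GTPase Gem (2.92 ± 0.29 SE), Adamts1 and Slc51a (a subunit of the basolateral bile acid transporter, 2.72 ± 0.35 SE). They were followed by the calcium-binding protein gene S100g (2.34 ± 0.43 SE), neurotensin (Nts, 2.34 ± 0.35 SE) and metallothionein 2 (Mt2, 2.30 ± 0.31 SE). The largest falls were Tppp (a tubulin-binding protein, −2.15 ± 0.37 SE), Atp12a (−2.05 ± 0.21 SE), the hedgehog co-receptor Gas1 (−1.54 ± 0.33 SE) and Id4 (−1.41 ± 0.15 SE). They were followed by the Wnt receptor Fzd2 (−1.37 ± 0.15 SE), the chemokine receptor Cx3cr1 (−1.37 ± 0.18 SE) and Etfbkmt (−1.25 ± 0.20 SE). Smaller falls were those of Ccn2 (−1.23 ± 0.19 SE), the apelin receptor Aplnr (−1.18 ± 0.14 SE) and Hoxd13 (−1.15 ± 0.21 SE). Adjusted p over these 20 genes lay between 3.11e-06 and 0.0341. A dimmer probe set of Ptx3 had a log2 change of 0.11, and of the dimmer probe sets of Gas1 1 changed by −0.24. Leaving out 1 array ended the calls of Gas1 (for 8 of the 11 arrays, adjusted p up to 0.134), S100g (3, up to 0.0838), Tppp (2, up to 0.0548) and Hoxd13 (2, up to 0.0888).

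Of 15 measured glucocorticoid-induced genes, 10 rose and none fell, and 15 rose when adjusted over the list alone (camera adjusted p = 2.61e-23). With an estimated correlation the call held (adjusted p = 0.000167). Fkbp5 (log2 change 1.36 ± 0.11 SE), Zbtb16 (1.86 ± 0.19 SE), the kinase gene Sgk1 (1.90 ± 0.21 SE) and Errfi1 (1.38 ± 0.18 SE) had the smallest p. Of 27 ATF4 and unfolded protein response genes 7 rose and none fell, and 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000844; adjusted p = 0.534 with an estimated correlation). Among them were the amino acid transporter subunit Slc3a2 (0.96 ± 0.15 SE), the mitochondrial folate enzyme gene Mthfd2 (1.33 ± 0.22 SE), Ddit4 (1.03 ± 0.17 SE) and Chac1 (1.94 ± 0.37 SE). Immediate early genes, which growth signals induce within the hour, were called upward (camera adjusted p = 0.0189; adjusted p = 0.534 with an estimated correlation). Of 25, 6 rose and 2 fell, and 10 rose and 5 fell adjusted over the list alone. Nr4a2 (1.10 ± 0.11 SE), Maff (0.74 ± 0.12 SE) and Nr4a3 (1.35 ± 0.22 SE) rose, and Ccn2 and, named after its value was seen, Fos (−0.86 ± 0.15 SE) fell.

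Among 24 absorptive colonocyte markers 3 rose and none fell, and 8 rose adjusted over the list alone (camera adjusted p = 0.00216; adjusted p = 0.534 with an estimated correlation). The 3 were Slc51a, Tmigd1 (1.46 ± 0.23 SE) and the sodium channel subunit Scnn1g (1.37 ± 0.22 SE). Of 32 genes of xenobiotic metabolism and transport, the cytochrome P450 genes Cyp3a25 (1.23 ± 0.22 SE) and Cyp2c65 (1.60 ± 0.37 SE) rose, 4 adjusted over the list alone (camera adjusted p = 0.00153; adjusted p = 0.534 with an estimated correlation). Leaving out 1 array ended the calls of Cyp2c65 (for 8 of the 11 arrays, limma adjusted p up to 0.175) and Cyp3a25 (2, up to 0.0743). One of 13 targets of the oxidative stress factor NRF2 rose, Gclc (0.76 ± 0.15 SE), and 3 adjusted over the list alone (camera adjusted p = 0.000425; adjusted p = 0.301 with an estimated correlation). In the list of 34 antimicrobial and mucosal defence genes, the cytokines Il6 (1.52 ± 0.14 SE) and Cxcl1 (1.35 ± 0.29 SE) rose and Il18 (−0.72 ± 0.16 SE) fell. Adjusted over the list alone there were 7 rises and 1 fall (camera adjusted p = 0.00752; adjusted p = 0.534 with an estimated correlation). The calls of Il18 and Cxcl1 were lost when 1 array was left out, for 7 and 4 arrays (limma adjusted p up to 0.147 and 0.142). Of 19 cholesterol synthesis genes Hsd17b7 rose (0.89 ± 0.11 SE), also 1 adjusted over the list alone (camera adjusted p = 0.0193; adjusted p = 0.784 with an estimated correlation). None of 28 T and NK cell markers passed the test, in either adjustment, and 5 had an unadjusted limma p under 0.05. The list was called upward (median log2 change 0.12; camera adjusted p = 0.0202; adjusted p = 0.534 with an estimated correlation), a call lost without control replicate 1 (camera adjusted p = 0.0873) and without 3 h replicate 3 (0.193). Without control replicate 2 the calls of the antimicrobial genes (camera adjusted p = 0.0642), the cholesterol synthesis genes (0.0674) and the immediate early genes (0.109) were lost. The call of the cholesterol synthesis genes was also lost without 3 h replicate 1 (0.0789) and 4 (0.075).

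The list of 29 G2 and mitosis genes was called downward at 3 h (median log2 change −0.50; camera adjusted p = 3.96e-07; adjusted p = 0.534 with an estimated correlation). The spindle checkpoint kinase gene Bub1b (−0.69 ± 0.14 SE) and Hmmr (−0.78 ± 0.17 SE) fell, 4 adjusted over the list alone, and Mki67 had a log2 change of −0.54 ± 0.20 (SE; limma adjusted p = 0.204). Leaving out 1 array ended the calls of Bub1b (for 5 arrays, limma adjusted p up to 0.127) and Hmmr (6, up to 0.118). The mean log2 level of the list on 3 h replicate 4, 7.19, lay within the control arrays' 7.09 to 7.37. Of 16 mesenteric fat markers, the fatty acid genes Scd1 (1.20 ± 0.19 SE) and Fabp4 (1.16 ± 0.21 SE) rose and none fell, 8 rises adjusted over the list alone (camera adjusted p = 3.01e-05; adjusted p = 0.534 with an estimated correlation). Of 10 posterior Hox genes, which mark the distal colon, Hoxb13 (−0.97 ± 0.17 SE), Hoxd13, Hoxa13 (−0.70 ± 0.15 SE) and Hoxd10 (−0.56 ± 0.13 SE) fell, 4 adjusted over the list alone (camera adjusted p = 0.000979; adjusted p = 0.301 with an estimated correlation). The test with fry called the list (fry adjusted p = 0.0237). Leaving out 1 array ended the calls of Hoxd10 (for 8 of the 11 arrays, limma adjusted p up to 0.135), Hoxa13 (6, up to 0.131) and Hoxb13 (1, 0.0785). The 13 anterior Hox and proximal colon genes as a list were not called at 3 h (camera adjusted p = 0.0713), but Osr2 (2.14 ± 0.42 SE) and Hoxb3 (0.78 ± 0.15 SE) in it rose, with a dimmer probe set of Osr2 at 0.10. With the fat markers as a covariate the 3 h call of the mitotic genes was lost (median 0.03, camera adjusted p = 0.527). So were those of the xenobiotic genes (0.05, 0.82), the absorptive markers (−0.13, 0.82) and the fat markers themselves (−0.10, 0.922). The immediate early genes (0.16, 0.35) and the T and NK cell markers (0.17, 0.186) lost their calls too. Their medians did not shrink in step, being 0.16 and 0.12 without the covariate. With the posterior Hox genes as a covariate the mitotic genes had a median of −0.21 and their call was lost (camera adjusted p = 0.0912). So were those of the immediate early genes (median 0.26, camera adjusted p = 0.0912), the absorptive markers (0.11, 0.0912) and the antimicrobial genes (0.11, 0.926). Without the covariate these medians were 0.16, 0.07 and 0.09, so they did not shrink. The xenobiotic genes (0.03, 0.926), the T and NK cell markers (−0.02, 0.949) and the posterior Hox genes themselves (0.04, 0.988) lost their calls too. The fat score was higher and the posterior Hox score lower on every 3 h array than on every control. Either covariate thus partly restates the group. The cholesterol synthesis call was lost with the pancreatic markers as a covariate (camera adjusted p = 0.0818). That of the T and NK cell markers was lost without the 5 arrays high in pancreatic transcripts (0.341). All of these alternatives were chosen after seeing the data.

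None of 16 measured Eph receptors and ephrins and none of 8 kinases that imatinib inhibits passed the limma test at 3 h, also 0 of each adjusted over the list alone. Unadjusted p was under 0.05 for 2 and 1 of them, and the test with fry gave adjusted p = 0.96 and 0.627 for the lists. Log2 changes were −0.16 ± 0.21 (SE) for Ccnd1, −0.21 ± 0.15 (SE) for Abl1, 0.31 ± 0.12 (SE) for Abl2, −0.29 ± 0.15 (SE) for Ephb3 and −0.29 ± 0.11 (SE) for Ephb4. They were 0.01 ± 0.16 (SE) for Kit, −0.14 ± 0.17 (SE) for Pdgfra, −0.46 ± 0.24 (SE) for Pdgfrb and −0.48 ± 0.17 (SE) for the stem cell marker Lgr5. Probe sets of the same gene differed, with log2 changes from −0.21 to 0.46 over 3 for Abl1 and from −0.48 to 0.09 over 2 for Lgr5. Ephb2 was not analysed here. In the list of 18 G1 cyclins and regulators, Myc rose by 0.89 ± 0.17 (SE; limma adjusted p = 0.0181) and the cell cycle inhibitor Cdkn1b fell by 0.74 ± 0.14 (SE; limma adjusted p = 0.016). The Myc call was lost without control replicate 1 or 2 (limma adjusted p up to 0.0855). Adjusted over the list alone 3 rose and 1 fell. The number of genes called at 3 h was 172 and 161 without control replicates 1 and 2, and 260, 223, 223 and 281 without 3 h replicates 1 to 4. It was 140 with the fat markers as a covariate and 6 with the posterior Hox genes as a covariate, both chosen after seeing the data. The posterior Hox score was lower on every 3 h array (5.71 to 5.99) than on every control (6.13 to 6.42). The fat score was higher on every 3 h array than on every control. Both covariates thus partly restate the group, and the loss of calls does not show their cause.

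**Figure D1:**
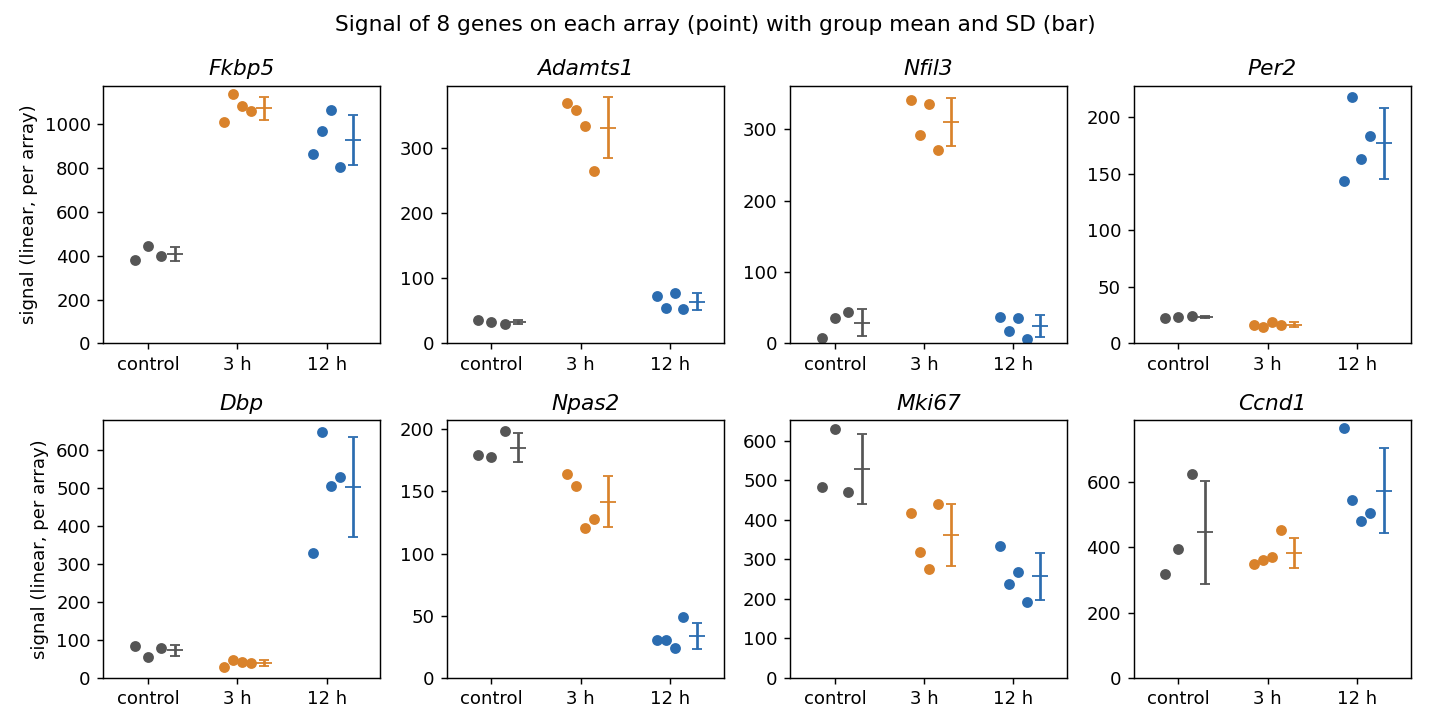
Signal on a linear axis from 0 for 8 genes, with a point for each array of the control (n = 3), 3 h (n = 4) and 12 h (n = 4) groups and a bar for the group mean and SD. Fkbp5, Adamts1 and Nfil3 were higher on every 3 h array than on every control array, Per2 and Dbp were higher and Npas2 lower on every 12 h array, Mki67 fell at 12 h, and the Ccnd1 signals of each treated group overlapped those of control.

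The comparison at 12 h asked what differed from control at the later time. Clock genes that peak with Per and Dbp were higher. Per2 went from 23.4 ± 1.11 (SD, n = 3) to 176.8 ± 31.8 (SD, n = 4), a log2 change of 2.28 ± 0.12 (SE; limma adjusted p = 6.96e-06), and Dbp from 72.4 ± 14.8 (SD, n = 3) to 502.3 ± 131 (SD, n = 4). Npas2, a partner of the clock activator Bmal1, fell from 185.3 ± 11.5 (SD, n = 3) to 33.5 ± 10.6 (SD, n = 4). Of 28 fibroblast and matrix markers 12 fell, among them collagen and elastin genes, of 29 G2 and mitosis genes 7 fell, and of 19 cholesterol synthesis genes 5 rose. The calls of these 3 lists by camera were lost with an estimated correlation (adjusted p = 0.114, 0.315 and 0.174 with an estimated correlation). The test with fry called all 3 (fry adjusted p = 0.002, 0.0468 and 0.0116).

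At 12 h 143 genes rose and 154 fell (limma, adjusted p under 0.05), 47 and 26 of them at least 2-fold. After each array was shifted to an equal median 165 rose and 115 fell. The largest rises were Dbp (log2 change 2.53 ± 0.20 SE), Slc51a (2.52 ± 0.35 SE), the transcription factor Osr2 (2.40 ± 0.42 SE), S100g (2.37 ± 0.43 SE) and Per2. They were followed by Tspan4 (2.26 ± 0.22 SE), the apical bile acid transporter Slc10a2 (2.25 ± 0.26 SE), lipocalin 2 (Lcn2, 2.21 ± 0.48 SE), Cyp4b1 (2.15 ± 0.41 SE) and the sulfate transporter Slc13a1 (1.94 ± 0.31 SE). The largest falls were endothelin 1 (Edn1, −2.17 ± 0.29 SE), Npas2 (−2.05 ± 0.16 SE), the phosphate transporter Slc34a2 (−2.01 ± 0.19 SE) and Ypel2 (−1.95 ± 0.19 SE). They were followed by the magnesium channel Trpm6 (−1.88 ± 0.27 SE), Bnip5 (−1.80 ± 0.17 SE) and the ubiquitin ligase Rnf125 (−1.61 ± 0.14 SE). Smaller falls were those of Sectm1a (−1.55 ± 0.33 SE), the tight junction gene Cldn8 (−1.49 ± 0.18 SE) and elastin (Eln, −1.38 ± 0.18 SE). Adjusted p over these 20 genes lay between 6.96e-06 and 0.0424. A dimmer probe set had a log2 change of 0.15 for Osr2, 0.20 for Slc13a1 and −0.20 for Ypel2. Leaving out 1 array ended the calls of Lcn2 (for 10 of the 11 arrays, adjusted p up to 0.155), Sectm1a (9, up to 0.167), Cyp4b1 (4, up to 0.11), Osr2 (3, up to 0.0883), S100g (3, up to 0.101) and Slc13a1 (2, up to 0.0757).

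Of 11 clock genes that peak with Per and Dbp, 6 rose and none fell, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.05e-13). With an estimated correlation the call held (adjusted p = 0.0438). Besides Per2 and Dbp, Tef (1.94 ± 0.13 SE) and Ciart (1.51 ± 0.13 SE) rose, with a dimmer probe set of Tef at 0.04. Of 5 clock genes that peak with Bmal1, Npas2 and the Bmal1 gene Arntl (−1.30 ± 0.11 SE) fell, with 1 rise and 3 falls adjusted over the list alone (camera adjusted p = 0.00202; adjusted p = 0.174 with an estimated correlation). Of the 15 glucocorticoid-induced genes 3 rose at 12 h, Fkbp5 (1.15 ± 0.11 SE), Sgk1 (1.47 ± 0.21 SE) and Lcn2, whose call was lost without any of 10 of the 11 arrays, and 4 adjusted over the list alone (camera adjusted p = 0.00146; adjusted p = 0.0916 with an estimated correlation).

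Among 28 fibroblast and matrix markers 12 fell and none rose, and 23 fell and 1 rose adjusted over the list alone (camera adjusted p = 5.28e-18; adjusted p = 0.114 with an estimated correlation). Col6a3 fell by 1.18 ± 0.13 (SE), Col3a1 by 0.73 ± 0.11 (SE), Col1a2 by 0.72 ± 0.12 (SE) and Eln as above. In the list of 24 smooth muscle markers Casq2 (−0.67 ± 0.14 SE) passed the test alone, with 9 falls adjusted over the list alone (median −0.46; camera adjusted p = 2.01e-09; adjusted p = 0.642 with an estimated correlation). The median signal of that list was 727 on 12 h replicate 4, within the control arrays' 658 to 855, and 281 to 372 on the other 3 arrays at 12 h. The Casq2 call was lost without any of 8 of the 11 arrays (limma adjusted p up to 0.145). The 29 G2 and mitosis genes had 7 falls and no rise, and 23 falls adjusted over the list alone (median −0.74; camera adjusted p = 7.42e-18; adjusted p = 0.315 with an estimated correlation). Among them were Mki67 (−1.01 ± 0.20 SE; limma adjusted p = 0.029), Bub1b (−0.75 ± 0.14 SE), Hmmr (−0.90 ± 0.17 SE) and Anln (−0.98 ± 0.20 SE). The Mki67 call was lost without control replicate 1 or 2 or 12 h replicate 2 or 3 (limma adjusted p up to 0.13). Leaving out 1 array also ended the calls of Anln (for 8 of the 11 arrays, limma adjusted p up to 0.143), Bub1b (4, up to 0.115) and Hmmr (4, up to 0.105). None of 27 S phase genes passed in either adjustment, 5 had an unadjusted limma p under 0.05, and the list was called downward (median −0.25; camera adjusted p = 0.0191; adjusted p = 0.707 with an estimated correlation). Of 19 cholesterol synthesis genes 5 rose and none fell, 15 rises adjusted over the list alone (camera adjusted p = 2.8e-14; adjusted p = 0.174 with an estimated correlation). Log2 changes were 0.67 ± 0.12 (SE) for Pmvk, 0.62 ± 0.11 (SE) for Hsd17b7, 1.10 ± 0.21 (SE) for Lss and 0.83 ± 0.16 (SE) for Idi1.

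Of the 24 absorptive colonocyte markers 4 rose at 12 h, Slc51a, Scnn1g (1.53 ± 0.22 SE), Tmigd1 and Guca2b (0.80 ± 0.17 SE), and 7 adjusted over the list alone (camera adjusted p = 0.0191; adjusted p = 0.707 with an estimated correlation). Among the 13 anterior Hox and proximal colon genes Osr2, Hoxb3 (0.78 ± 0.15 SE) and Hoxb6 (1.19 ± 0.26 SE) rose, 3 adjusted over the list alone (camera adjusted p = 0.0237; adjusted p = 0.315 with an estimated correlation). Leaving out 1 array ended the calls of Hoxb6 (for 8 of the 11 arrays, limma adjusted p up to 0.174) and Hoxb3 (4, up to 0.105). The median of the 10 posterior Hox genes was 0.05, and none of them passed or had an unadjusted p under 0.05. Dnajb1 rose among 16 heat shock genes (0.81 ± 0.14 SE), 5 adjusted over the list alone (camera adjusted p = 0.0237; adjusted p = 0.707 with an estimated correlation). Fabp4 rose among 16 fat markers (1.11 ± 0.21 SE), 1 adjusted over the list alone (camera adjusted p = 0.0237; adjusted p = 0.707 with an estimated correlation). The 35 interferon-stimulated genes were called upward with no member past the test in either adjustment and 3 with an unadjusted limma p under 0.05 (median 0.36; camera adjusted p = 0.000297; adjusted p = 0.707 with an estimated correlation). Their median was −0.01 without 12 h replicate 1 (camera adjusted p = 0.999) and 0.18 without control replicate 1 (0.0983). Calls were also lost for the heat shock genes without control replicates 1 and 2 (camera adjusted p = 0.0976 and 0.116) and 12 h replicates 1 and 4 (0.123 and 0.062). The absorptive markers had a median of 0.01, with 12 members higher and 12 lower. Their call was lost and their median below 0 without control replicate 2 (−0.04; 0.0555) and 12 h replicates 3 and 4 (−0.04 and −0.03; 0.076 and 0.0856). The S phase call was lost without control replicate 3 (0.547) and 12 h replicates 3 and 4 (0.057 and 0.32). For the fat markers these same 3 arrays gave 0.121, 0.0532 and 0.528, and for the anterior Hox genes control replicate 1 and 12 h replicates 3 and 4 gave 0.0677, 0.057 and 0.123. With the fat markers as a covariate the S phase median went to −0.01 and the call was lost (camera adjusted p = 0.98). The absorptive markers (median −0.13, 0.433), the fat markers (0.06, 0.875) and the anterior Hox genes (0.18, 0.153) lost their calls too. With the pancreatic markers as a covariate the S phase (median −0.21, camera adjusted p = 0.0673) and absorptive (−0.04, 0.0515) calls were lost. Leaving out the 5 arrays high in pancreatic transcripts leaves 1 array at 12 h. The median of the interferon-stimulated genes was then −0.236. The heat shock (median 0.034), absorptive (−0.138), fat (−0.074) and anterior Hox (0.125) calls were lost. These 3 alternatives were chosen after seeing the data.

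None of the 16 Eph receptors and ephrins passed the limma test at 12 h in either adjustment, and 3 had an unadjusted p under 0.05. As a list they had a median of 0.06 and were not called by camera (adjusted p = 0.476), but the test with fry called them upward (adjusted p = 0.0398). Among the 8 kinases that imatinib inhibits, Csf1r, the receptor of macrophage growth factor, fell by 0.53 ± 0.12 (SE; limma adjusted p = 0.0441), and 1 fell adjusted over the list alone. Log2 changes that did not pass were 0.38 ± 0.21 (SE) for Ccnd1, 0.11 ± 0.15 (SE) for Abl1, −0.03 ± 0.12 (SE) for Abl2, −0.23 ± 0.15 (SE) for Ephb3 and 0.08 ± 0.11 (SE) for Ephb4. They were −0.22 ± 0.16 (SE) for Kit, −0.04 ± 0.17 (SE) for Pdgfra, −0.22 ± 0.24 (SE) for Pdgfrb, −0.06 ± 0.17 (SE) for Lgr5 and −0.20 ± 0.17 (SE) for Myc. Over the 3 probe sets of Abl1 log2 changes lay between −0.06 and 0.43. Cdkn1b fell by 0.71 ± 0.14 (SE; limma adjusted p = 0.0268). The number of genes called at 12 h was 75 and 64 without control replicates 1 and 2, 141 and 110 without 12 h replicates 2 and 3, and 455 without 12 h replicate 4. It was 62 with only these 7 arrays in the fit, 196 with pancreatic markers as a covariate and 8 without the 5 arrays high in pancreatic transcripts, the last 2 chosen after seeing the data.

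**Figure D2:**
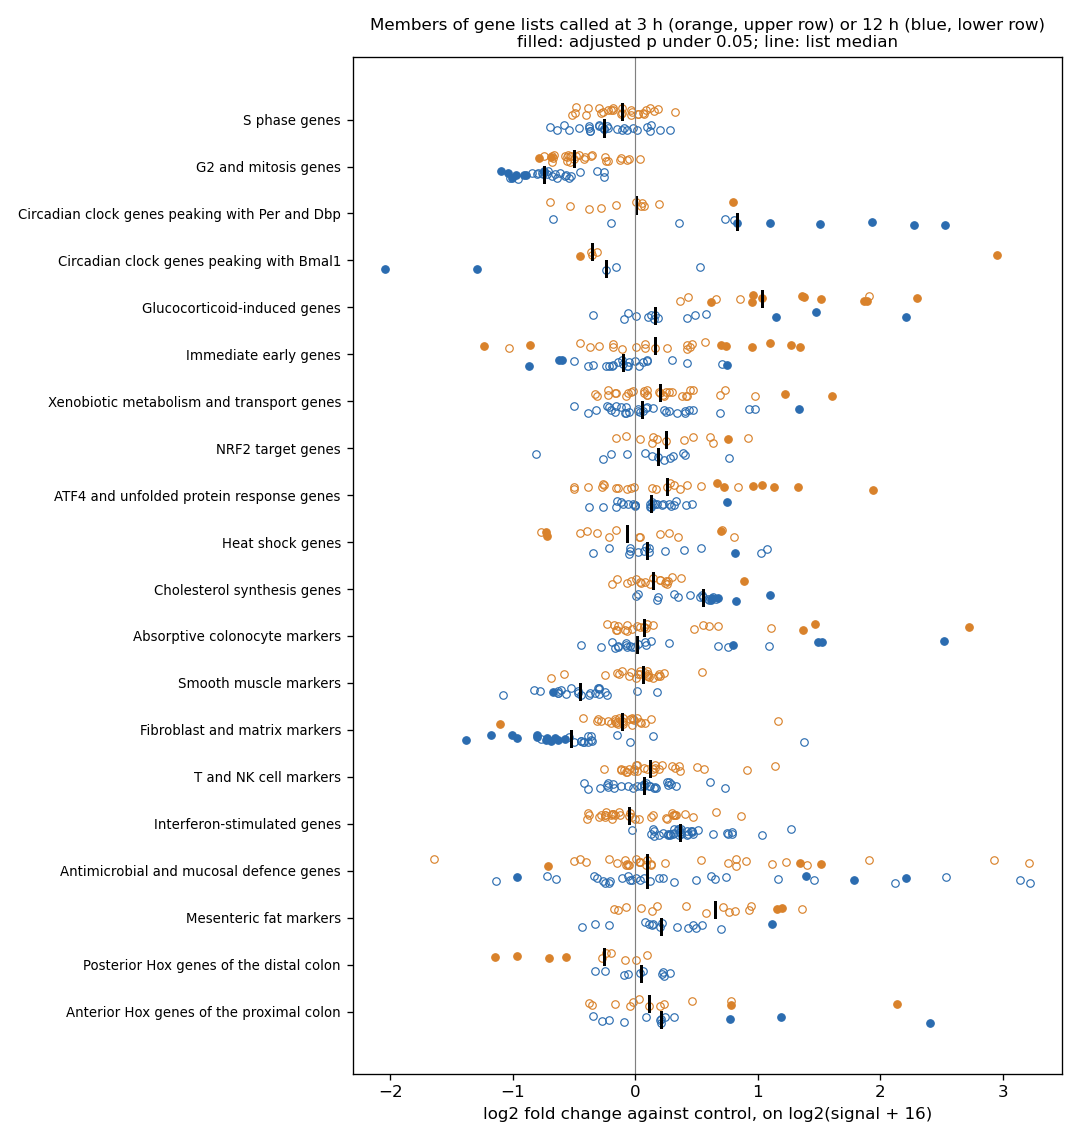
Log2 fold change against control of each measured member of the gene lists called at 3 h or 12 h, on the log2(signal + 16) scale, with 3 h in orange above and 12 h in blue below. Filled points passed the limma test, open points did not, and black lines are list medians, which for glucocorticoid-induced genes were 1.03 at 3 h and 0.16 at 12 h.

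The direct comparison of 12 h with 3 h tested whether the changes at both times differed, since the control cancels. The hours of harvest of these groups are not given and may differ. A difference here therefore joins the time after the injection and the hour of harvest. Genes chosen by their changes at 3 h or 12 h are tested here on the same treated arrays. That selection favours a difference, also for the genes called at either time and the 4 posterior Hox genes below. Of the 10 genes with the largest rises at 3 h, 7 were lower at 12 h than at 3 h, while Slc51a, S100g and Nts did not pass this test (limma adjusted p = 0.826, 0.983 and 0.577). Log2 changes were −3.11 ± 0.31 (SE) for Nfil3, −2.87 ± 0.24 (SE) for Adamts4, −2.68 ± 0.19 (SE) for Ptx3, −2.59 ± 0.27 (SE) for Gem, −2.29 ± 0.18 (SE) for Kcne4, −2.12 ± 0.13 (SE) for Adamts1 and −1.88 ± 0.28 (SE) for Mt2. Clock genes were among the 10 largest rises, with Dbp at 3.22 ± 0.19 (SE), Per2 at 2.55 ± 0.11 (SE), Tef at 1.93 ± 0.12 (SE) and Ciart at 1.31 ± 0.12 (SE). Atp12a went from 455.4 ± 54.5 (SD, n = 4) at 3 h to 2797 ± 840 (SD, n = 4) at 12 h, a log2 change of 2.53 ± 0.20 (SE; limma adjusted p = 2.7e-05).

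In this comparison 362 genes rose and 379 fell (limma, adjusted p under 0.05), 21 and 80 of them at least 2-fold. Other large rises were Tspan4 (1.48 ± 0.20 SE), Cys1 (1.34 ± 0.11 SE), Lefty1 (1.34 ± 0.11 SE), Mab21l2 (1.33 ± 0.15 SE) and Cx3cr1 (1.26 ± 0.17 SE). Other large falls were Edn1 (−2.42 ± 0.27 SE), the protease gene Adamts9 (−2.13 ± 0.16 SE), Sprr1a (−1.96 ± 0.31 SE) and the calcium channel Trpv6 (−1.92 ± 0.21 SE). A dimmer probe set had a log2 change of 0.03 for Ptx3, 0.00 for Tef, 0.08 for Cys1 and −0.02 for Adamts9. Of the 462 genes called at 3 h, 199 differed between 12 h and 3 h. Of the 297 called at 12 h, 106 differed from 3 h.

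Of the glucocorticoid-induced genes 9 of 15 fell, 11 adjusted over the list alone, among them Zbtb16 (−1.29 ± 0.17 SE) and Errfi1 (−1.23 ± 0.17 SE). That list was called with either correlation (camera adjusted p = 1.03e-12; adjusted p = 0.00158 with an estimated correlation). So were the Per and Dbp clock genes, of which 5 of 11 rose, 8 adjusted over the list alone (camera adjusted p = 7.14e-12; adjusted p = 0.0285 with an estimated correlation). Of 5 Bmal1 clock genes Npas2 (−1.69 ± 0.14 SE), Nfil3 and Arntl (−0.98 ± 0.11 SE) fell and Cry1 (0.88 ± 0.18 SE) rose, 3 and 2 adjusted over the list alone (camera adjusted p = 0.00954; adjusted p = 0.271 with an estimated correlation). Immediate early genes had 7 falls and 2 rises of 25, 13 and 4 adjusted over the list alone, with Nr4a2 at −1.15 ± 0.10 (SE) and Nr4a3 at −1.42 ± 0.20 (SE) (camera adjusted p = 0.000454; adjusted p = 0.315 with an estimated correlation). Fibroblast and matrix markers differed (camera adjusted p = 1.66e-12; adjusted p = 0.215 with an estimated correlation). Of 28, 13 fell and Bmp4 (0.96 ± 0.11 SE) rose, 21 and 2 adjusted over the list alone, and Col6a3 had a log2 change of −1.08 ± 0.12 (SE). Smooth muscle markers had 3 falls of 24, 18 falls and 1 rise adjusted over the list alone, with Des at −0.88 ± 0.19 (SE) and Actg2 at −0.76 ± 0.17 (SE) (camera adjusted p = 5.79e-10; adjusted p = 0.504 with an estimated correlation). On 12 h replicate 4 the list's median signal of 727 lay within the 643 to 858 of the 3 h arrays. Of 19 cholesterol synthesis genes 5 rose, 14 rises and 1 fall adjusted over the list alone, among them Idi1 (0.79 ± 0.15 SE) and Mvd (0.57 ± 0.12 SE; camera adjusted p = 3.12e-07; adjusted p = 0.427 with an estimated correlation). Of 16 heat shock genes Chordc1 (1.13 ± 0.12 SE), Dnaja1 (0.93 ± 0.12 SE) and Dnajb1 (0.79 ± 0.13 SE) rose and Hspb8 (−0.75 ± 0.12 SE) fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.00954; adjusted p = 0.663 with an estimated correlation). The 4 posterior Hox genes that had fallen at 3 h were higher at 12 h than at 3 h, by 0.88 ± 0.16 (SE) for Hoxb13, 0.90 ± 0.20 (SE) for Hoxd13, 0.65 ± 0.14 (SE) for Hoxa13 and 0.80 ± 0.12 (SE) for Hoxd10. Of the 10 in that list 4 rose, 5 adjusted over the list alone (camera adjusted p = 4.88e-05; adjusted p = 0.108 with an estimated correlation). Lists called with no member past the limma test were the 29 G2 and mitosis genes (median −0.26; camera adjusted p = 9.13e-05; adjusted p = 0.783 with an estimated correlation) and the 13 NRF2 targets (median −0.22; camera adjusted p = 0.0431; adjusted p = 0.504 with an estimated correlation). Adjusted over the list alone, 0 of the mitotic genes passed, 5 having an unadjusted p under 0.05, and 1 rise and 2 falls of the NRF2 targets did. The NRF2 call was lost without control replicates 1 to 3 (camera adjusted p = 0.0585, 0.0738 and 0.0538), where the median stayed at −0.22. It was also lost without 3 h replicates 1 and 4 (0.08 and 0.0645) and 12 h replicates 1 and 3 (0.127 and 0.0651). These medians lay between −0.28 and −0.14. The interferon-stimulated genes were also called with no member past the test, 8 having an unadjusted p under 0.05 (median 0.45; camera adjusted p = 0.00639; adjusted p = 0.867 with an estimated correlation), and without 12 h replicate 1 their median was −0.01 (camera adjusted p = 0.746). With the fat markers as a covariate the calls of the interferon-stimulated genes (median 0.08, camera adjusted p = 0.613), the heat shock genes (0.30, 0.0607) and the NRF2 targets (−0.10, 0.071) were lost. With the posterior Hox genes as a covariate the call of the cholesterol synthesis genes was lost (median 0.15, camera adjusted p = 0.213). Those of the smooth muscle markers (−0.275, 0.185) and the posterior Hox genes themselves (0.04, 0.981) were lost too. So were those of the Bmal1 clock genes (−1.30, 0.0712) and the NRF2 targets (−0.27, 0.257), whose medians were −0.98 and −0.22 without the covariate. With the pancreatic markers as a covariate the Bmal1 clock (median −1.02, camera adjusted p = 0.0503) and NRF2 (−0.21, 0.241) calls were lost. Without the 5 arrays high in pancreatic transcripts the NRF2 (0.329), heat shock (0.0894) and interferon (0.629) calls were lost.

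Myc fell between 3 h and 12 h by 1.09 ± 0.16 (SE; limma adjusted p = 0.00265), and Ccnd1 was higher at 12 h by 0.55 ± 0.20 (SE; limma adjusted p = 0.157) without passing. Values for Mki67 (−0.47 ± 0.18 SE), Abl1 (0.31 ± 0.14 SE), Abl2 (−0.33 ± 0.11 SE), Ephb3 (0.06 ± 0.14 SE), Ephb4 (0.36 ± 0.10 SE), Kit (−0.23 ± 0.15 SE), Lgr5 (0.42 ± 0.16 SE), Pdgfra (0.10 ± 0.16 SE) and Pdgfrb (0.24 ± 0.22 SE) did not pass either. Log2 changes of single probe sets went from −0.03 to 0.31 for Abl1, from −0.33 to 0.08 for Abl2 and from −0.08 to 0.42 for Lgr5. The number of genes called between the times was 395, 417, 450 and 442 without 3 h replicates 1 to 4 and 412 without 12 h replicate 2. It was 352 with pancreatic markers, 342 with fat markers and 4 with posterior Hox genes as a covariate, all chosen after seeing the data. The posterior Hox score was higher on every 12 h array (6.26 to 6.30) than on every 3 h array (5.71 to 5.99). That covariate thus partly restates the group, and the loss of calls does not show their cause.

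Some genes were called against control at both times. Of the calls against control, 52 genes rose and 36 fell at both 3 h and 12 h, where independent lists would share 2.1 and 1.7. In opposite directions 2 genes were called. Genes named above that rose at both times included Slc51a, S100g, Osr2, Nts, Fkbp5, Sgk1, Slc10a2, Cyp4b1, Tmigd1, Scnn1g, Fabp4, Hoxb3 and Hsd17b7. Adamts1 did too, with a log2 change of 0.71 at 12 h (limma adjusted p = 0.0337). Among those that fell at both were Cdkn1b, Ccn2, Aplnr, Etfbkmt, Ypel2, Bnip5, Bub1b and Hmmr. Across genes, which are not independent replicates, the fold changes at 3 h and 12 h correlated with r = 0.457 and a covariance of 0.0355. Simulated groups without change, sharing 3 simulated controls, gave a mean r of 0.571 and a covariance of 0.0182 over 20 simulations. The difference in covariance was 0.0173. The noise was drawn independently for each gene and array, controls included. Variation that many genes of a real control array share was therefore not simulated. The simulations called at most 1 gene at each time, so they do not show how many of the genes called here would overlap through the shared controls. The 3 controls are too few to split between the times, and part of the excess may come from the shared controls.

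Transcripts of other tissues and the added control RNA also differed between arrays. The median signal of 16 pancreatic acinar markers, a list chosen after seeing the data, was 8730 on control replicate 1, 1780 on 3 h replicate 3, and 6670, 4310 and 2000 on 12 h replicates 1, 3 and 4, and lay between 7.25 and 100 on the other 6 arrays. The elastase gene Cela3b ranged from 7.5 to 11600 and the trypsinogen gene Prss2 from 7 to 10700, while Cela1, also in the list, lay between 2067.9 and 11272 on the 11 arrays. Poly-A control RNA relative to the hybridisation controls was higher than in control by 1.24-fold at 3 h and 1.76-fold at 12 h (log2 difference 0.31 and 0.82), with no overlap between the arrays of the groups. The exact permutation test, 2-sided, gave p = 0.0286 for each, the smallest that 3 against 4 arrays can give, and a Benjamini-Hochberg adjusted value of 0.103 over 18 tests. Between 12 h and 3 h the log2 difference was 0.51, with no overlap and the same p and adjusted value. Handling of the RNA may thus have differed between the groups, and the gene comparisons cannot separate it from the treatment.

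**Figure D3:**
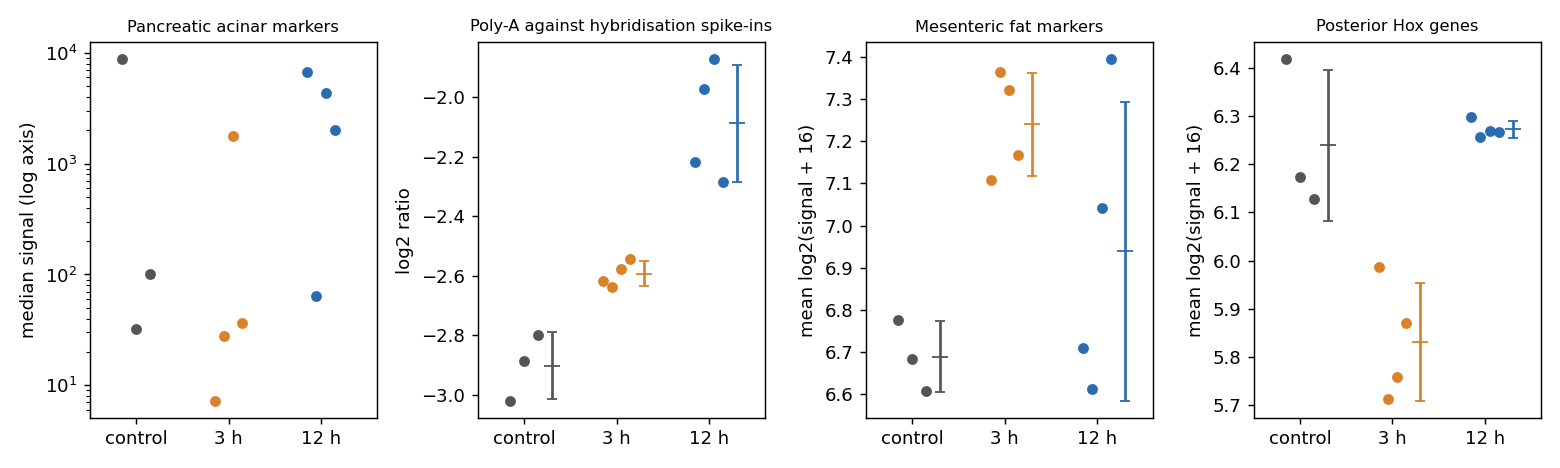
Values of each array by group: median signal of 16 pancreatic acinar markers on a log axis, log2 ratio of poly-A to hybridisation control RNA, and mean log2(signal + 16) of fat markers and of posterior Hox genes. Bars show the group mean and SD (n = 3, 4 and 4), and 5 arrays have acinar signals of 1780 or more.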

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

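The tests of the share of epithelium, of the fat markers against the mitotic genes, of the hour of harvest or injection, of the proximal genes at 12 h and of dilution by other tissue were chosen only after the results were seen. The acinar and fat scores used as covariates in the other tests below were also added after seeing the data. Among 35 splits of the 7 arrays for 3 h against control, 1, the real one, gave 462 or more genes, and the highest of the others gave 0. For 12 h against control 1 of 35 splits gave as many as 297, again the real one, and the highest other gave 179, when 12 h replicate 4 was placed with the controls. For 12 h against 3 h 1 of 35 splits gave as many as 741 and the highest other gave 0. In each contrast 1 of 35 is the smallest share that such splits can give. It makes chance less likely as the source of the counts but does not exclude it.

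The mitotic genes were lower after imatinib, with a median log2 change of −0.50 at 3 h and −0.74 at 12 h, though 2 and 7 of 29 passed the limma test and the list's calls were lost with an estimated correlation (adjusted p = 0.534 and 0.315). The test with fry gave adjusted p = 0.311 at 3 h and 0.0468 at 12 h. Pancreatic RNA is argued against for 12 h, since the median was −0.67 with the acinar score as a covariate (−0.85 to −0.55 when any 1 array was left out). Absorptive colonocyte markers had a median of 0.01 and a lower quartile of −0.09 at 12 h, with 12 higher and 12 lower. These values argue against a smaller share of absorptive cells. Medians at 12 h were −0.03 for goblet, 0.08 for enteroendocrine and 0.09 for tuft cell markers, and 0.16 for stem cell and Wnt target genes. Camera called none of these lists, so they show no fall like that of the mitotic genes. Epithelial cells that none of these lists marks are not covered, so a smaller share of those stays open. At 3 h, variation shared with the fat markers remains a candidate explanation: with the fat score as a covariate the median went to 0.03 (−0.09 to 0.31 when any 1 array was left out), although the fat score was also higher on every 3 h array than on every control, and with the posterior Hox score as a covariate the median was −0.21 (camera adjusted p = 0.0912). At 12 h it was −0.54 with the fat score as a covariate (−0.67 to −0.31), which leaves the fat variation open. The hour of harvest or injection rather than the drug cannot be told apart from the drug, because there were 0 vehicle-injected arrays at the same hours.

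Posterior Hox genes were lower at 3 h, and the 4 called had a median log2 change of −0.84 (adjusted p = 0.301 for the list of 10 with an estimated correlation). The test with fry gave adjusted p = 0.0237 for that list. Each of the 4 lost its call when some single array was left out, Hoxd10 for 8 arrays and Hoxa13 for 6. Dilution by fat or other tissue is argued against, since smooth muscle markers had a median of 0.06 and absorptive colonocyte markers one of 0.07, each with a lower quartile of −0.07. Another stretch of colon in the samples stays open for 3 h: the deviations of posterior and proximal scores within groups had r = −0.44 and rho = −0.32 over 11 arrays (permutation test within groups, 1-sided, p = 0.145 and 0.165), and r = −0.27 without the 2 arrays farthest from the median, control replicate 1 and 3 h replicate 1. It is argued against as the source of the proximal genes at 12 h, where the same 4 Hox genes had a median of −0.07 (−0.11 to −0.01 when any 1 array was left out).

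Glucocorticoid-induced genes were higher at 3 h, with a median log2 change of 1.03. Fat carried in the samples is argued against as the whole cause, since the median was 0.81 with the fat score as a covariate (0.70 to 0.88 when any 1 array was left out). Handling and injection rather than the drug cannot be told apart from the drug, since there were 0 vehicle-injected arrays at the same hours.

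Some results differed between the 3 h and 12 h groups by the direct test, 741 genes in all. Of the named genes the log2 change from 3 h to 12 h was −2.68 for Ptx3, −2.29 for Kcne4, −2.87 for Adamts4, −3.11 for Nfil3, −2.59 for Gem, −2.12 for Adamts1, −1.88 for Mt2, 2.53 for Atp12a, 1.10 for Id4, 1.22 for Fzd2, 1.26 for Cx3cr1, 0.90 for Hoxd13, −1.09 for Myc, 3.22 for Dbp, 2.55 for Per2, 1.48 for Tspan4, −2.42 for Edn1, −1.69 for Npas2, −1.38 for Slc34a2, −0.97 for Ypel2, −1.32 for Trpm6, −0.83 for Bnip5, −1.77 for Rnf125, −1.73 for Cldn8 and −1.27 for Eln. Of the lists, the median change from 3 h to 12 h was −0.26 for G2 and mitosis genes, 0.75 for Per and Dbp clock genes, −0.98 for Bmal1 clock genes, −0.73 for glucocorticoid-induced genes, −0.30 for immediate early genes, −0.22 for NRF2 targets, 0.25 for heat shock genes, 0.35 for cholesterol synthesis genes, −0.51 for smooth muscle markers, −0.50 for fibroblast and matrix markers, 0.45 for interferon-stimulated genes and 0.32 for posterior Hox genes. With an estimated correlation the calls of the glucocorticoid-induced genes (adjusted p = 0.00158) and the Per and Dbp clock genes (0.0285) held and those of the other 10 lists were lost (adjusted p from 0.108 for posterior Hox genes to 0.867 for interferon-stimulated genes). Without 12 h replicate 1 the interferon median was −0.01.

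Single arrays stood far from the others of their group in 13 of 202 tests of the gap to the nearest array over the range of the group, where chance, which marks about 1 in 20, gives 10.1. The ratio was 0.853 for S100g on 12 h replicate 3, 0.831 for Tppp, 0.865 for Lgr5, 0.863 for Cys1 and 0.864 for Sprr1a on 12 h replicate 4, and 0.874 for Kit on 12 h replicate 2. It was 0.832 for Cyp4b1 and 0.878 for Mab21l2 on 3 h replicate 1, 0.852 for Cyp4b1 on 12 h replicate 1, and 0.907 for Adamts9 on 3 h replicate 2. Among the lists it was 0.907 for interferon-stimulated genes (mean log2 level 8.67 against 6.84 to 7.01) and 0.864 for MHC class II genes (7.96 against 6.79 to 6.95) on 12 h replicate 1, and 0.870 for skeletal muscle markers on 3 h replicate 2 (5.09 against 5.14 to 5.15).

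In data outside the gene comparisons, poly-A control RNA relative to hybridisation controls was above control by 0.31 (log2) at 3 h and 0.82 at 12 h. Of 10092 probe sets without a single gene symbol, 9 passed the limma test at 3 h against control, 7 upward and 2 downward. Between 12 h and 3 h 4 passed upward and 7 downward, and at 12 h against control 0 passed, 698 having an unadjusted p under 0.05.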

How the results depend on the processing

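The number of called genes depended on the processing. The direction of each called named gene held under every alternative that kept a single value per gene, except for Hoxd13 between 12 h and 3 h. The cause of each change below was not tested unless stated. In the order 3 h against control, 12 h against control and 12 h against 3 h, the counts of 462, 297 and 741 genes became 878, 690 and 1275 at an adjusted p under 0.10, 229, 81 and 436 with an offset of 1, and 93, 2 and 358 with a two-sample test per gene that shares no variance. They were 80, 8 and 16 without the 5 arrays high in pancreatic transcripts, which leaves 2, 3 and 1 arrays in the groups, so that the lone 12 h array is assumed to vary like the others. With the upper 60% of genes by level, which tests fewer genes, 706 and 545 were called at 3 h and 12 h. At 12 h the count was 536 with a trended and robust variance prior, 492 with an offset of 64, 196 with the acinar score as a covariate and 62 with only the 7 arrays compared. Between 12 h and 3 h it was 386 with a 1.5-fold minimum, and 352, 342 and 4 with the acinar, fat and posterior Hox scores as covariates, and at 3 h it was 140 and 6 with the fat and posterior Hox scores. On the fat and posterior Hox scores every 3 h array lay outside the control range. On the posterior Hox score every 3 h array lay outside the 12 h range too. Such covariates partly restate the groups, so the loss of calls was in part set beforehand. Leaving out 1 array gave 161 to 520 genes at 3 h, 64 to 455 at 12 h and 395 to 758 between them, with fewer arrays in each fit. The 12, 13 and 12 called lists became 1, 1 and 2 with an estimated correlation, 2 and 8 at 3 h and 12 h with fry, 7 at 3 h with the posterior Hox score as a covariate, and 12 to 15, 9 to 16 and 11 to 15 when 1 array was left out. The correlation of fold changes across genes ranged from 0.385 to 0.568 when 1 array was left out. Offsets, covariates and the pancreatic arrays were chosen after seeing the data.

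With the replicate number as a block, 277, 183 and 466 genes were called. The numbers do not show a pairing of the samples: of 10 same-numbered pairs 3 had a correlation of deviations over 0.1 (range −0.207 to 0.311), and 4 samples correlated best with their own number. The median of the interferon-stimulated genes changed sign at 12 h against control without 12 h replicate 1 (−0.006) and without the pancreatic arrays (−0.236), and between 12 h and 3 h likewise (−0.008 and −0.029), and went up to 0.532 and 0.569 when another array was left out. The median of the fat markers at 12 h was −0.074 without the pancreatic arrays, that of the mitotic genes at 3 h was 0.026 with the fat score, and that of the T and NK cell markers at 3 h was −0.021 with the posterior Hox score. The median of the absorptive markers at 12 h, 0.011, fell below 0 without control replicate 2 (−0.035), 12 h replicate 3 (−0.041) or 12 h replicate 4 (−0.029), with array weights (−0.02), without the pancreatic arrays (−0.138) and with the acinar (−0.041) and fat (−0.127) scores, while camera's direction stayed upward. The alternatives on other tissue and region ended list calls too, for 3 h, 12 h and 12 h against 3 h in 6, 4 and 3 lists with the fat score, 1, 2 and 2 with the acinar score, 7, 0 and 5 with the posterior Hox score and 1, 4 and 3 without the pancreatic arrays. With the fat score the medians of the absorptive markers (−0.129) and of the fat markers themselves (−0.096) at 3 h also changed sign, as did that of the posterior Hox genes at 3 h with their own score (0.04). Hoxd13 between 12 h and 3 h was −0.056 with the posterior Hox score, a covariate that contains Hoxd13. Leaving out 1 array ended the call of 49 gene values, with Lcn2 at 12 h (10 of 11 arrays, adjusted p up to 0.155) and Sectm1a and Guca2b at 12 h (9 arrays each, up to 0.167) the most often, and Mki67 at 12 h with 4 arrays (up to 0.13). Over the named genes and their alternatives, 585 values lost and 104 gained the call with the direction kept, 4880 stayed on their side and 1 called value changed direction. A change of sign between values that were not called counts among the 4880. Signal over background limits dim genes: 32.9% of genes had a mean below the level of the offset.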

Other observations

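The test of the FoxO hypothesis was written before the values of the genes tested were seen, apart from their not being called at both times, and the choice of the antimicrobial and male accessory gland genes was made after. Some genes differed between arrays of the same group. The antimicrobial lectin genes Reg3b and Reg3g had signals of 497.6 and 25.2 on control replicate 1 and of 150 and 67.6 on control replicate 2, against 6114 and 1841 on control replicate 3 and 3604 or more for Reg3b on each treated array. Their log2 changes at 3 h were 2.93 ± 0.87 (SE; limma adjusted p = 0.111) and 3.21 ± 1.06 (SE; limma adjusted p = 0.153), so neither passed the test. The male accessory gland markers had a median signal of 55.8 on 3 h replicate 4, 39.3 on control replicate 3 and 23.5 on control replicate 2, and between 1.2 and 7.7 on the other arrays.

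Of the 41 lists, 21 were not called in any of the 3 contrasts, with lowest camera adjusted p between 0.0511 and 0.93. They include Eph receptors and ephrins (0.476), kinases that imatinib inhibits (0.581), G1 cyclins (0.92), stem cell and Wnt target genes (0.146), goblet cell markers (0.553), tuft cell markers (0.468), endothelial markers (0.477), macrophage and dendritic cell markers (0.0511) and cytosolic ribosomal protein genes (0.563).

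Irs1, Klhl24, Fbxo32, Cdkn1b and Hbp1, named after their values were seen, fell at both times and are known targets of FoxO transcription factors, which insulin and PI3K signalling hold out of the nucleus. A change in insulin or PI3K signalling to FoxO may lie behind this, as a hypothesis. The other FoxO targets examined were 26 that were not called at both times. Their median log2 change was 0.06 at 3 h and −0.02 at 12 h, and camera with an estimated correlation gave p = 0.297 at 3 h and 0.462 at 12 h. At 3 h Bcl2l11 (1.35 ± 0.19 SE; limma adjusted p = 0.00377) and Bcl6 (0.69 ± 0.11 SE; limma adjusted p = 0.00653) rose. At 12 h the smallest adjusted p was 0.0511, for Irs2 (−0.97 ± 0.22 SE), and these 3 genes are named after their values were seen. Leaving out genes called at both times tilts this set towards no change, so its values do not decide, and the hypothesis stays open.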
